A study of Lens culinaris with 20 samples.

How the data were processed

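Small RNA was profiled in 7 tissues of lentil (Lens culinaris), a grain legume: roots, shoots, mature leaves, stem, flowers, young pods and flower buds. Each tissue had 3 libraries except flowers, with 2, which made 20 libraries. Per the labels' protocols, total RNA was taken from pooled samples with TRI Reagent and a Spectrum Plant Total RNA kit, and libraries were made with a TruSeq Small RNA kit. The labels do not say whether the libraries of a tissue came from separate plants or pools, so p-values measure only the spread between these libraries, which may be technical. The read trimming, the aligner, the miRNA caller and the genome build are not given in the sources used here.

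The deposited table holds 1642 mature miRNA entries with a name, a mature sequence and, for most, a precursor sequence. Another 7 lines of the table are not reported here. Per the file headers, one set of columns is raw. These are expected counts (estimated read counts) as the authors deposited them: 25.8% of the values above 0 were not whole numbers, to a tolerance of 0.01. Such fractions were more frequent in entries whose sequence stood more than once (53.2%) than in other entries (10.5%), so the authors shared reads among entries. Per the file headers, the other set of columns is normalized. These values are a signal that the authors made by multiplying each raw column by 1 factor per library, and how that factor was found is not given in the sources used here. Each factor, taken as normalized over raw, was used only as an alternative scaling. The table also has a lower limit. Among 1146 unshared entries that were whole throughout, the most frequent value above 0 was 5 reads (786 of 3892 values), 13 values lay under it and 0 values were 1 or 2 reads. A value of 0 therefore stands for fewer than about 5 reads, not for absence.

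Entries with the same mature sequence were collapsed to 1 feature, keeping the entry with the highest total, which left 1464 features. This rule was fixed before the data were examined on the assumption that repeated entries count the same reads. The shared reads go against that assumption, so summing the entries was added as an alternative. Counts were rounded to whole numbers. A family is the number in the miRNA name, with miR157 counted in miR156, miR165 in miR166 and miR170 in miR171. By this rule 394 features fell into 80 families and 1070 had no family. Names are printed as the table gives them, with a species prefix of a known miRNA or the prefix lcum. A feature was called exact when its sequence lay unchanged in its listed precursor, with the unread base N of 17 sequences taken to match any base, which held for 842 features, did not hold for 579 and could not be asked for 43. No genome was used here, so no positions are given.

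Library totals ran from 72853 to 997119 reads. Features were filtered with edgeR's filterByExpr by tissue, which kept 323, and libraries were scaled by TMM, with factors from 0.508 to 1.71. Levels are CPM, the reads scaled to the TMM-adjusted library size, so their sum differs between libraries. Tests were edgeR's quasi-likelihood F-tests over all 20 libraries with tissue as the only term (edgeR 4.0.16, limma 3.58.1, R 4.3.3). Each tissue was compared with the mean of the other 6 on the log2 scale. Tissues near 0 weigh strongly in such a mean, so a miRNA can be called higher where its mean CPM is not. Where 1 of the other 6 tissues is at 0 in every library, the fitted mean has no lower limit, so the test cannot call a miRNA lower. Reproductive tissues (flowers, flower buds and young pods) were compared with vegetative ones, flowers with flower buds, and roots with shoots. A call required a Benjamini-Hochberg adjusted p under 0.05 over all features tested and an absolute log2 fold change of at least 1. Family tests used counts summed over a family's features, for 54 families, so a family level can add the reads of both arms of a precursor. The targets named for a family were not checked for each arm. Of the 1464 features, 610 repeated the counts of another feature in every library. Family sums kept such repeats and were not retried without them, so a family level may hold the same reads more than once. The error after a log2 fold change is its standard error, and the error after a CPM is the SD over libraries. No fitted fold change is given for a miRNA listed at 0 in every library of a tissue in the comparison. Where one side of a comparison was listed at 0 throughout, the fold is a lower bound against 5 reads per library. Such bounds cover counting error only. The tau index, on tissue means of log2(CPM + 1), runs from 0 for equal levels to 1 for a single tissue, with a threshold of 0.85. Shares of reads by mature length were compared with a two-sided permutation test of the F statistic with 100000 resamples. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for these shares and for the plots.

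The miRNAs named in the text follow a rule fixed before the data were examined. For each tissue these are the 6 called higher and the 4 called lower with the largest change, and for the other comparisons up to 10 in each direction. The higher side had to reach a mean of 10 CPM, every library of one side had to lie beyond the mean of the other, and at most 1 feature per family and direction was taken. The 10 most abundant features and every family of 9 fixed lists may also be named. Those lists are phase change and flowering, auxin and tasiRNA, developmental transcription factors, copper, phosphate and sulfate, triggers of phased siRNAs (NB-LRR), small RNA machinery, legume families, and animal miRNA families as a sign of RNA from another organism. Other families named were chosen after their values were seen.

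The edgeR tests were tried on simulated counts with known changes. For roots, 53.3% of 4-fold and 81.3% of 16-fold changes were recovered, and 8 of 125 unchanged features were called. For reproductive against vegetative tissues, 72.7% and 87.4% were recovered, with 4 of 129 unchanged features called. For flowers against flower buds only 28.4% and 58.1% were recovered, with 0 of 108 unchanged features called. The length test was tried on simulated shares, drawn independently from a normal distribution, and not on counts. It found 20 of 20 changes, all large against the simulated spread, and called 4 of 60 unchanged shares. Its power for small changes was therefore not tested.

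Alternatives fixed before the data were examined were DESeq2's size factors and library size alone as scalings, DESeq2 1.42.0 as the test, no filter, a stricter filter (10 CPM in 2 libraries), every entry as its own feature, the replicate number as a block, fits on the compared tissues only, and leaving out each library. Alternatives chosen after seeing the data were the authors' factors, summed entries, features of identical counts collapsed, exact features only, and every library thinned to 72853 reads. Replicates were compared within each tissue: no 2 libraries held identical values, and chi-square per degree of freedom lay between 6.86 and 340. No library was therefore dropped as a copy of another. Such values measure spread beyond counting error and cannot tell separate samples from technical repeats of the same RNA.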

Results

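The series profiled miRNAs across 7 lentil tissues to ask which miRNAs mark each organ. There were 3 libraries each of roots, shoots, mature leaves, stem, young pods and flower buds, and 2 of flowers. Reads assigned to mature miRNAs totalled 72853 to 150453 in the root libraries, 105279 to 326712 in shoots, 74113 to 531473 in mature leaves, 203195 to 756217 in stem, 232271 and 997119 in flowers, 196984 to 453847 in young pods, and 197952 to 600487 in flower buds. Rare miRNAs could be read down to about 5 reads, which equalled 61.0 CPM in mature leaves 3 and 4.03 CPM in flowers 2.

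miR166, which targets HD-ZIP III transcription factors, was the most abundant family. Its main member mtr-miR166a (TCGGACCAGGCTTCATTCCCC, 21 nt) averaged 249464 CPM over the tissues, from 117585 CPM in stem to 519568 CPM in flower buds. It was followed by mtr-miR159a (TTTGGATTGAAGGGAGCTCTA, mean 114385 CPM), of a family that targets MYB factors, and by ath-miR164a (TGGAGAAGCAGGGCACGTGCA, mean 56911 CPM), of a family that targets NAC factors. The other 7 of the 10 most abundant features belonged to miR319, miR398 (both arms), miR166, miR390 and miR8175. Both of the miR166 features among these had the same level in every tissue and differed only by an unread first base, and both entered the family sum. The miR8175 feature, of 18 nt, had no listed precursor. Whether it is a miRNA or a fragment of another RNA was therefore not tested. Over all 7 tissues 240 of 323 features and 46 of 54 families differed (edgeR quasi-likelihood F-test, 256 features at an unadjusted p under 0.05). Replicates correlated at Spearman 0.846 to 0.957 within a tissue. Roots stood apart, at 0.385 to 0.663 to the libraries of other tissues, while the other 6 tissues correlated at 0.684 or more with one another.

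**Figure D1:**
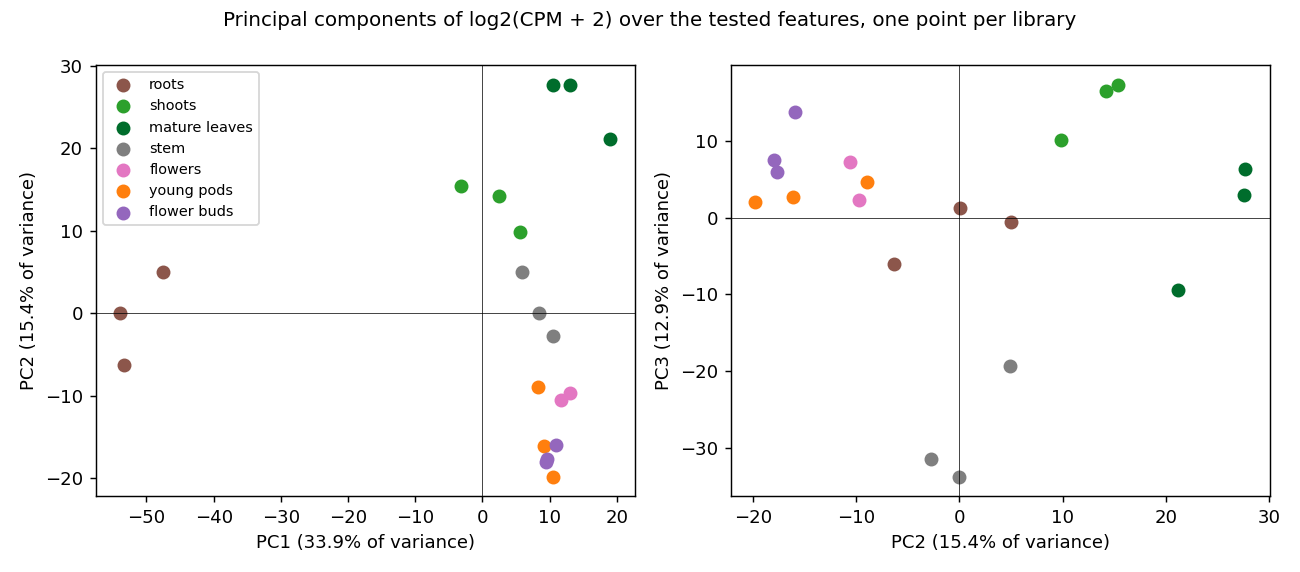
Principal components of log2(CPM + 2) over the 323 tested features, with 1 point per library coloured by tissue; the left panel plots component 1 (x axis, 33.9% of variance) against component 2 (y axis, 15.4%), and the right panel component 2 (x axis) against component 3 (y axis, 12.9%). The 3 root libraries sit alone at the low end of component 1, and mature leaves and shoots lie at the high end of component 2.

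**Figure D2:**
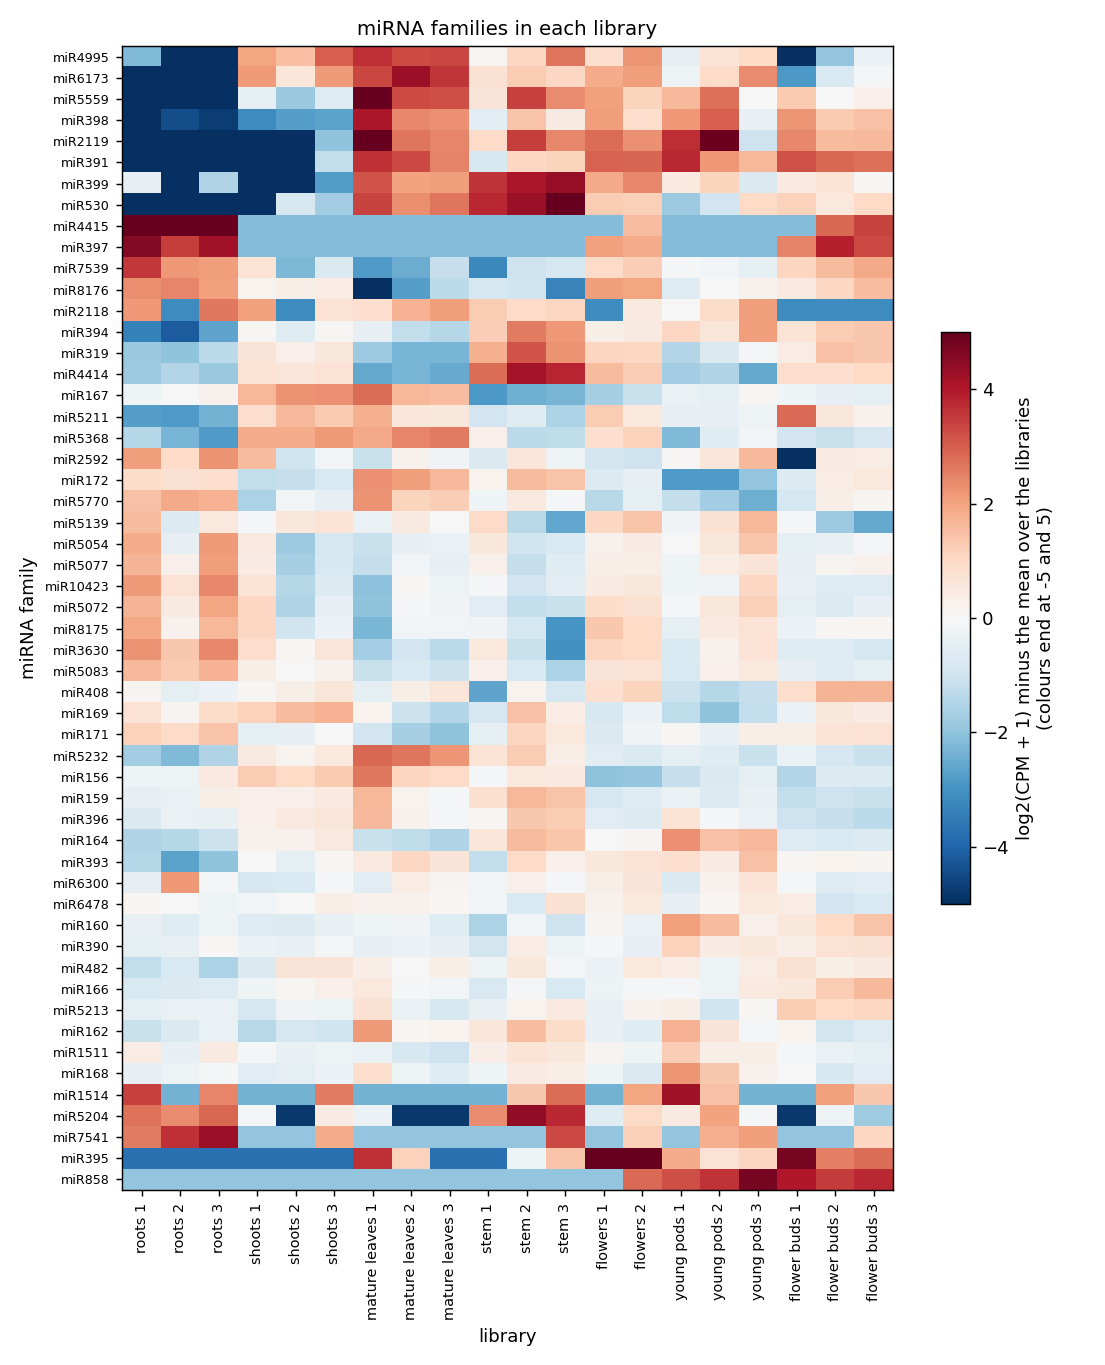
Each family tested (54 lines) in each of the 20 libraries (columns), as log2(CPM + 1) minus its mean over the libraries, red above and blue below the mean, with colours ending at -5 and 5. The root columns show low miR398 and high miR4415, the stem columns high miR4414 and miR319, and the leaf columns high miR5232.

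Roots were set against the mean of the other 6 tissues. miR398, which targets copper/zinc superoxide dismutases, was at 849 ± 204 CPM (SD, n = 3) in roots against 204157 ± 153288 CPM in mature leaves, or 115704 CPM without mature leaves 1 (log2 fold change -5.81 ± 0.68, adjusted p = 1.75e-07). miR394, which targets an F-box gene, fell by 3.90 on the log2 scale, miR393, which targets auxin receptors, by 2.39, and miR319, which targets TCP factors, by 2.10. miR5559 and miR391 were listed at 0 in all 3 root libraries, at least 62.5-fold and 12.8-fold below the mean of the other tissues. The miR5559 bound was 34.6-fold without mature leaves 1 and 40.3-fold without roots 3. The laccase regulator miR397 was at 78.9 ± 29.4 CPM in roots, 44.2 ± 21.02 CPM in flower buds and 16.5 ± 1.71 CPM (n = 2) in flowers, and was listed at 0 in the other 4 tissues. Similarly, miR4415 reached 822 ± 163 CPM in roots, 25.8 ± 23.3 CPM in flower buds (15.9 CPM without flower buds 3) and 6.04 ± 8.54 CPM in flowers (0 in flowers 1), and was at 0 elsewhere.

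Of the 5 auxin and tasiRNA families 2 fell in roots (miR164 and miR393) and 3 did not pass. Of 8 families for developmental transcription factors, 1 rose (miR171, 1.36 ± 0.28), 3 fell (miR164, miR319 and miR394) and 4 did not pass. Among 3 copper families miR397 rose, miR398 fell and miR408 did not pass. miR399, of phosphate homeostasis, was at 45.03 ± 46.1 CPM (21.5 CPM without roots 1) and fell (-2.41 ± 0.72). Without shoots 3, the 1 shoot library in which it was above 0, no lower call was possible (adjusted p = 0.9997). miR395, at 0 throughout roots and shoots, could not be called lower either. miR482, which targets NB-LRR resistance genes, fell (-1.40 ± 0.32) and miR2118 was called higher, at 30.7 ± 27.7 CPM, near the limit of 5 reads (46.1 CPM without roots 2 and 19.2 CPM without roots 3). The miR2118 level was that of a single feature of 18 nt, osa-MIR2118e-p3_1ss13TA. Whether that feature triggers phased siRNAs was not tested. Of the 6 legume families tested, miR2119, miR4414 and miR5232 fell and 3 did not pass. Neither miR156 nor miR172 passed, nor did miR162 or miR168 of the small RNA machinery. Adjusted over the list alone, all these counts were the same.

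Of 323 features 104 were higher and 64 lower in roots. The 6 named as highest all lacked a family and were listed at 0 in every other library, led by lcum-miR-4489_3445-3p at 7561 ± 2806 CPM, at least 337-fold above the rest, and lcum-miR-14113_1065-5p at 3214 ± 448 CPM, at least 143-fold. In total 21 features without a family were seen in all root libraries only, and 20 of them did not lie exactly in their listed precursor. Features of 18 and 19 nt held 10.4% to 25.96% of root reads, against 0.866% to 12.4% in the other libraries. The split depended on the scaling, at 85 higher and 83 lower with DESeq2's size factors, 123 and 42 with library size, and 80 and 90 with the authors' factors. Calls of miR171 and miR2118 were lost with DESeq2's and the authors' factors, that of miR2118 also without any of 9 single libraries (adjusted p up to 0.105), those of miR164 and miR482 with library size, and that of miR482 without roots 3 (log2 fold change 0.98 in size). Both miR391 and miR2119 were at 0 in shoots 1 and 2, so without shoots 3 the test could not call them lower (adjusted p = 0.9997 and 0.9997). With exact features only, 94 calls were left, 48 higher and 46 lower.

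**Figure D3:**
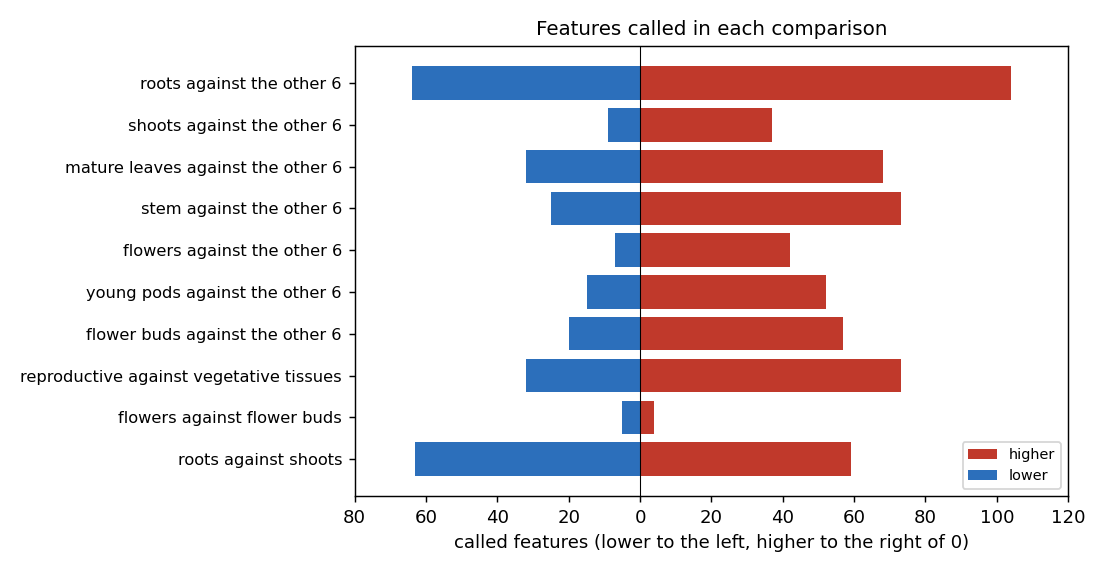
Number of features called in each of the 10 comparisons (bars; x axis, features called lower to the left of 0 and higher to the right), by edgeR at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. Roots have the most calls, 104 higher and 64 lower, and flowers against flower buds the fewest, 4 higher and 5 lower.

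In shoots miR167, which targets auxin response factors, was at 55839 ± 12332 CPM (SD, n = 3), a level also reached in mature leaves (56756 ± 29053 CPM), against 2264 ± 425 CPM in stem (log2 fold change over the mean of the other 6 tissues 2.48 ± 0.22, adjusted p = 1.69e-09). Its 22 nt member ath-miR167d_1ss22GA was at 42372 ± 11032 CPM (3.19 ± 0.25). miR156, which targets SPL factors and keeps shoots juvenile, was at 122177 ± 14977 CPM (1.45 ± 0.27), and in mature leaves at 181189 ± 127346 CPM (107729 CPM without mature leaves 1), and miR172, which targets AP2-like factors, was at 2387 ± 449 CPM (-1.23 ± 0.34), so 1 family of the phase change list rose and 1 fell. miR398 fell by 3.60 on the log2 scale and miR399 by 5.27, with miR399 at 5.60 ± 9.71 CPM and above 0 in shoots 3 alone.

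In shoots 1 of 5 auxin and tasiRNA families rose (miR167), and miR160, miR164, miR390 and miR393 did not pass. Among the developmental list miR169, which targets NF-YA factors, rose (1.67 ± 0.42) and 7 families did not pass. Of 3 copper families 1 fell (miR398), and of 2 phosphate and sulfate families 1 fell (miR399). miR395 and miR397, at 0 throughout shoots and also throughout other tissues, could not be called lower. miR162, which targets a Dicer-like gene, fell (-1.33 ± 0.44), and miR168 did not pass. None of the 3 families of the phased siRNA list or the 6 legume families passed. The counts adjusted over the list alone were the same. Among features without a family, lcum-miR-23592_602-3p rose to 2986 ± 1306 CPM (3.63 ± 0.57), and lcum-miR-70562_122-3p, of 24 nt, was at 513 ± 277 CPM against 225 ± 108 CPM (n = 2) in flowers, or 149 CPM without flowers 2. In all, edgeR called 37 features higher and 9 lower. There were 25 calls without shoots 2 and 26 without shoots 3. The miR169 call was lost without either of these libraries (adjusted p up to 0.0733) and the miR162 call without shoots 1 or shoots 3 (up to 0.0893).

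In mature leaves miR398 and miR156 were among the most abundant families, at 204157 ± 153288 CPM and 181189 ± 127346 CPM (SD, n = 3), with log2 fold changes over the other 6 tissues of 3.42 ± 0.37 and 2.11 ± 0.26. miR172 rose to 19852 ± 4501 CPM (2.34 ± 0.26), miR167 to 56756 ± 29053 CPM (2.50 ± 0.22), and the legume family miR5232 to 24574 ± 5503 CPM (3.06 ± 0.23, adjusted p = 2.39e-11). miR319, at 7563 ± 1683 CPM, fell by 2.61 on the log2 scale, and miR164, at 19819.6 ± 2628 CPM, by 1.53. miR4414, whose sequence lies on the 5′ arm of the same listed precursor as a miR319 member, fell with it (-2.99 ± 0.40). miR5559 was at 8523 ± 9524 CPM in leaves and 1868 ± 1484 CPM in stem (1081 CPM without stem 2) and at 0 in roots.

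Both phase change families rose in leaves. In the auxin list miR167 rose, miR164 fell and 3 did not pass, and in the developmental list 4 of 8 fell (miR164, miR171, miR319 and miR394) and 4 did not pass. miR398 alone of 3 copper families rose. miR399 rose to 705 ± 334 CPM (2.21 ± 0.49) and miR395 was called higher, at 63.8 ± 87.2 CPM, though the mean over the other 6 tissues was 106 CPM. Mature leaves 2 and 3 had 28.3 and 0 CPM of it, under their limits of 47.2 and 60.97 CPM for 5 reads. miR162 was called higher (1.23 ± 0.36) and miR168 did not pass. Of 6 legume families miR2119 and miR5232 rose, miR4414 fell and 3 did not pass, and none of 3 families in the phased siRNA list passed. Adjusted over the list alone the counts were unchanged. Of 323 features 68 were higher and 32 lower (56 and 42 with library size alone).

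The library mature leaves 1 had the lowest TMM factor, 0.508, and over the 10 most abundant families its median log2 ratio to the other 2 leaf libraries was 0.97. Without it the leaf means were 115704 CPM for miR398, 107729 CPM for miR156, 3025 CPM for miR5559, 584 CPM for miR2119 and 14.2 CPM for miR395. That of miR162 fell under the mean of the other tissues (3337 against 3377 CPM). Without it 76 features were called, and the calls of miR399 and miR2119 (adjusted p = 0.0812 and 0.0578) and of miR156 (log2 fold change 0.91) were lost. Those of miR162 and miR395 were lost with library size alone, and without any of 13 and 15 single libraries (adjusted p up to 0.650 and 0.713). The miR394 call was lost with the authors' factors, and without mature leaves 2 or 3 (up to 0.0859).

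Stem had the highest levels of miR319, at 189449 ± 93502 CPM (SD, n = 3) against 7563 ± 1683 CPM in mature leaves (log2 fold change over the other 6 tissues 2.81 ± 0.25, adjusted p = 5.38e-10). miR4414, from the opposite arm of a miR319 precursor, was at 11768 ± 4975 CPM (4.21 ± 0.25). miR399 rose to 2077 ± 511 CPM (4.02 ± 0.45), miR394 to 6870.00 ± 3028 CPM (2.35 ± 0.31) and miR159 to 254044 ± 72886 CPM (1.56 ± 0.26). miR530 was at 1061 ± 459.6 CPM in stem, 346 ± 135 CPM in mature leaves and 0 in roots. miR167 fell by 2.92 on the log2 scale, to 2264 ± 425 CPM, and ath-miR160a-5p_L+2R-1, a 22 nt form of miR160, was listed at 0 in all 3 stem libraries, at least 5.96-fold below the mean of the other tissues.

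In stem 5 of 8 families of the developmental list rose (miR159, miR164, miR319, miR394 and miR396) and 3 did not pass. miR172 rose (1.36 ± 0.28) and miR156 did not pass. Of the auxin list miR164 rose (1.42 ± 0.22), miR167 fell and 3 did not pass. miR399 rose and miR395 did not pass, and miR162 rose (1.16 ± 0.36) and miR168 did not. Of 6 legume families miR4414 rose, miR2119 was called higher and 4 did not pass. The miR2119 mean of 609 CPM (359 CPM without stem 2) did not exceed that of the other tissues (649 CPM), which included roots at 0 and shoots at 7.85 ± 13.6 CPM. No copper family and no family of the phased siRNA list passed, with 3 tested in each. Adjusted over the list alone, these counts did not change. Of 323 features 73 were higher and 25 lower. The calls of miR162 and miR396 (1.14 ± 0.28) were lost with library size alone, that of miR396 also without stem 3 (log2 fold change 0.90), and that of miR2119 without stem 2 (adjusted p = 0.180).

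In flowers the sulfate-related miR395 was at 416 ± 6.57 CPM (SD, n = 2), against 172 ± 156 CPM (n = 3) in flower buds and 0 in roots and shoots. miR156 was at its lowest, 13540.5 ± 673 CPM (-2.26 ± 0.43 on the log2 scale, adjusted p = 5.17e-04), and miR167 was at 5165 ± 1382 CPM (-1.53 ± 0.36). miR319 was called higher (1.10 ± 0.32), though its mean CPM was higher in stem and in flower buds. miR398, miR399 and miR4414 were called higher (1.59 ± 0.46, 1.82 ± 0.56 and 1.54 ± 0.32), but as mean CPM they were hardly above or under the other 6 tissues, at 69056 against 69587 CPM (41081 CPM without flowers 1), 562 against 529 CPM and 2416 against 2600.4 CPM. mtr-miR156b-5p was at 4179.6 ± 367 CPM (-2.24 ± 0.47).

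In the phase change list miR156 fell and miR172 did not pass, and in the auxin list miR167 fell and 4 did not pass. Of the developmental list miR319 was called higher and 7 did not pass. Of 3 copper families 2 were called higher (miR397 and miR398), and 3 adjusted over the list alone. The miR397 mean, 16.5 CPM, was under that of the other tissues (20.5 CPM) and under the 5-read limit of every root, shoot and leaf library (16.8 to 60.97 CPM). Both phosphate and sulfate families were called higher. miR4414 was the 1 legume family of 6 called higher, and 2 were adjusted over the list alone. No family of the phased siRNA list (3 tested) and neither miR162 nor miR168 passed. In the other lists the count adjusted over the list alone was the same. Features called numbered 42 higher and 7 lower, which rested on 2 libraries. There were 30 calls without flowers 2, 81 without mature leaves 1, 77 without stem 2 or young pods 3, and 74 without flower buds 2 or 3, and DESeq2 called 31. The calls of miR156 and miR398 were lost without flowers 1 (adjusted p = 0.0706 and 0.113), that of miR399 without flowers 2 (0.0890), that of miR397 without either (up to 0.0922), that of miR167 without flowers 1 or mature leaves 1 (up to 0.214) and that of mtr-miR156b-5p without flowers 1 or flowers 2 (up to 0.147).

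Young pods carried the most miR164, at 173449 ± 56775 CPM (SD, n = 3) against 19309 ± 3109 CPM in roots (log2 fold change over the other 6 tissues 2.13 ± 0.21, adjusted p = 8.58e-09). miR160, which targets auxin response factors, rose to 10611 ± 5689.8 CPM (1.65 ± 0.29), and miR168, which targets an Argonaute gene, to 56262 ± 35253 CPM (1.65 ± 0.28). miR398 rose to 99861 ± 81827 CPM (2.22 ± 0.38), although its mean was higher in mature leaves. Of that miR398 level, 67933 CPM was the 5′ arm mtr-miR398a-5p_L-1R+1_1ss8CA. The 3′ arm ath-miR398a-3p_L+1R-1 was at 31697 CPM in pods, 35017.5 CPM in flowers and 101706 CPM in mature leaves. miR172 was at 868 ± 318 CPM, where it fell by 2.94 on the log2 scale, and miR4414 fell by 2.28. Within miR319 the members moved apart: gma-miR319d fell (-2.45 ± 0.41), while ath-miR319c_L+1R-1 rose, at 1861 ± 350.1 CPM in pods and 1368 ± 561 CPM in flower buds. ppe-miR858_1ss19TC, of a family that targets MYB regulators, was at 62.7 ± 37.5 CPM in pods (41.3 CPM without young pods 3), 52.5 ± 9.35 CPM in flower buds and 13.7 ± 19.4 CPM (n = 2) in flowers, where flowers 1 had 0, and at 0 in the 4 vegetative tissues.

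Of 5 auxin and tasiRNA families 3 rose in pods (miR160, miR164 and miR393) and 2 did not pass. In the developmental list miR164 and miR394 rose, miR169 fell and 5 did not pass, and in the phase change list miR172 fell and miR156 did not pass. Of copper families miR398 rose, miR408 fell (-1.57 ± 0.49) and miR397 did not pass. Both small RNA machinery families rose (miR162 and miR168). Of 6 legume families miR2119 was called higher and miR4414 fell, and no phosphate, sulfate or phased siRNA family passed. Adjusted over the list alone the counts were identical. Of 323 features 52 were higher and 15 lower.

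Young pods 3 differed from the other pod libraries, with miR398 at 17409.8 CPM against 101123 and 181050.04 CPM, and miR168 at 23524 CPM against 93583 and 51678 CPM. miR2119 was at 47.5 CPM there, under the mean of 509 CPM over the other tissues, against 1289.8 and 3018 CPM. Without young pods 2 the pod means were 669 CPM for miR2119 and 59266 CPM for miR398, the latter under the 64453 CPM of the other tissues. Without young pods 3 the miR394 call was lost (log2 fold change 0.96). The calls of miR162 and miR393 were lost with library size alone, and without any of 9 and 10 single libraries (adjusted p up to 0.415 and 0.244). The miR169 call was lost without young pods 2 (adjusted p = 0.0775) and the miR408 call without young pods 1 or 2 (up to 0.0775).

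In flower buds miR166 reached 703175 ± 240726 CPM (SD, n = 3), the highest level of any family in any tissue, against 186489 ± 9042 CPM in roots (log2 fold change over the other 6 tissues 1.39 ± 0.23, adjusted p = 1.31e-04). All 3 copper families were called higher. miR408 rose to 1769 ± 519 CPM (1.56 ± 0.38). miR398 was at 74129 ± 26112 CPM (1.71 ± 0.39), close to the mean of 68742 CPM over the other tissues, and miR397 at 44.2 ± 21.02 CPM, under the 5-read limits of mature leaves 2 and 3. miR5213, a phased siRNA trigger, rose to 2043 ± 206 CPM (1.23 ± 0.35), miR319 to 73610.4 ± 26648 CPM (1.22 ± 0.27) and miR160 to 7845 ± 2261 CPM (1.15 ± 0.30). miR159 and miR396, which targets growth-regulating factors, fell (-1.33 ± 0.32 and -1.38 ± 0.34).

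The developmental list thus split in buds, with 3 of 8 higher (miR166, miR319 and miR394), 2 lower (miR159 and miR396) and 3 not passing. Of 5 auxin families miR160 alone passed. miR156 fell (-1.001 ± 0.32) and miR172 did not pass. miR395 was called higher, at 172 ± 156 CPM, but without flower buds 1 its mean was 81.7 CPM, under the 87.6 CPM of the other tissues, and miR399 did not pass. In the phased siRNA list miR5213 rose, miR2118 was listed at 0 and called lower, and miR482 did not pass, and of 6 legume families only miR5213 passed. Neither small RNA machinery family passed. The counts adjusted over the list alone were equal to these. Of 323 features 57 were higher and 20 lower, a split of 84 and 13 with the authors' factors. Calls of miR319, miR394 and miR160 were lost with library size alone and those of miR156, miR159 and miR396 with the authors' factors, that of miR156 also with DESeq2's size factors and without any of 13 single libraries (adjusted p up to 0.239). miR159 lost its call without any of 4 libraries and miR396 without roots 2 or flowers 1 (log2 fold changes down to 0.92 and 0.97 in size), and miR2118 without flowers 2 or flower buds 3 (adjusted p up to 0.9998). Without flowers 2, miR2118 was at 0 throughout flowers, so no lower call was possible.

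**Figure D4:**
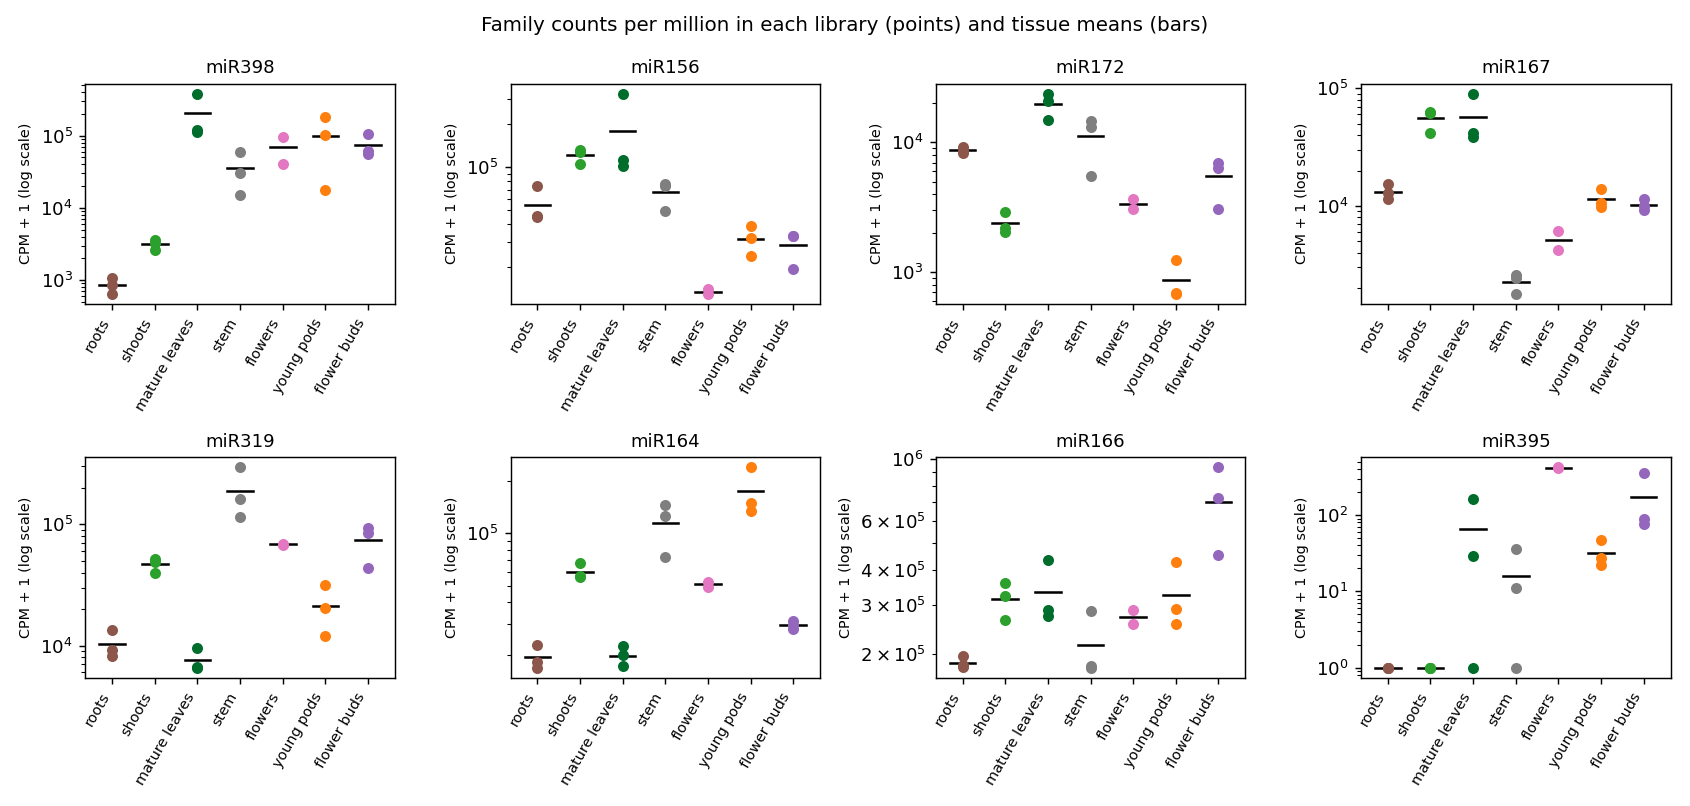
Levels of 8 families in each library (points; y axis, CPM + 1 on a log scale) by tissue (x axis), with bars at the tissue means. miR398 is lowest in roots (mean 849 CPM), miR156 lowest in flowers (mean 13540.5 CPM), miR319 highest in stem and miR164 highest in young pods.

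The 3 reproductive tissues were compared with the 4 vegetative tissues. Standard errors and p-values here come from the spread between libraries within a tissue, not between the tissues of a side. miR156 was lower in the reproductive tissues by 2.05 ± 0.24 on the log2 scale (SE, adjusted p = 2.43e-07) and miR172 by 1.71 ± 0.24, so both phase change families fell. mtr-miR156b-5p was at 5631 ± 3962 CPM (SD, n = 8) in reproductive libraries against a mean of 44296 CPM over the vegetative tissues. miR160 rose (1.32 ± 0.24). miR394 was called higher (1.51 ± 0.27), with means of 3224 against 2329 CPM, although stem had a higher mean than any reproductive tissue. miR398 was also called higher (2.76 ± 0.33): roots and shoots had little, but mature leaves had a higher mean than any reproductive tissue. In turn ath-miR167d_1ss22GA fell (-2.02 ± 0.24). ath-miR319c_L+1R-1 was at 1316 ± 591 CPM in reproductive libraries against 58.96 CPM, while another member of the same family, gma-miR319d, fell (-1.71 ± 0.26). lcum-miR-44629_253-5p was listed at 0 in all 12 vegetative libraries and was at least 3.81-fold higher in reproductive ones.

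Of 5 auxin families miR160 rose, miR167 fell (-1.06 ± 0.20) and 3 did not pass. In the developmental list miR394 was called higher, miR159 and miR169 fell (-1.37 ± 0.22 and -1.12 ± 0.36) and 5 did not pass. Of 3 copper families miR398 was called higher, and of 2 phosphate and sulfate families miR395 was called higher. Of 3 families in the phased siRNA list miR2118, with its single feature of 18 nt, was called lower, near the limit of 5 reads. Of 6 legume families miR2119 was called higher, miR5232 lower (-1.19 ± 0.21) and 4 did not pass, and neither small RNA machinery family passed. Among the listed families called, the tissue means of both sides lay fully apart for miR156, miR159 and miR160 and overlapped for miR167, miR169, miR172, miR394, miR395, miR398, miR2118, miR2119 and miR5232. Chance gives 5.71% for families taken without regard to a call. Called families were picked by the same means, so that share is no yardstick for them. Adjusted over the list alone the same counts were found. In all 73 features were higher and 32 lower (91 and 18 with the authors' factors). Calls of miR167, miR169 and miR5232 were lost with DESeq2's and the authors' factors, and that of miR159 with the authors' factors. Each was also lost without any of 15, 14, 8 and 4 single libraries respectively (log2 fold changes down to 0.53, 0.56, 0.74 and 0.86 in size), and that of miR2118 without flowers 1 or flower buds 2 or 3 (adjusted p up to 0.0879).

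Few miRNAs passed between flowers and flower buds, the stage before them. mtr-miR166a was at 218696 ± 23978 CPM (SD, n = 2) in flowers and 519568 ± 152571 CPM (n = 3) in buds (-1.25 ± 0.33 on the log2 scale, adjusted p = 0.0458). mtr-miR156e fell in flowers (-1.93 ± 0.45), while hbr-MIR6173-p3_1ss2GA and gma-MIR5368-p3_1ss15CA_2 were higher (3.73 ± 0.90 and 2.50 ± 0.55). By families miR166 fell (-1.37 ± 0.39) and miR4995, miR5368 and miR6173 rose (3.13 ± 0.96, 1.97 ± 0.51 and 2.80 ± 0.76). miR166 was the 1 developmental family of 8 that passed, and no family of the other lists did. Adjusted over the list alone, 1 phase change family and 1 auxin family were also lower. edgeR called 9 features, 4 higher and 5 lower, and 57 had an unadjusted p under 0.05. The split was 15 and 4 with library size and 5 and 13 with the authors' factors, and the calls of miR166 and mtr-miR166a were lost with library size. No feature was called without flowers 1 or flower buds 3, 1 without flower buds 2 and 2 without flowers 2, and all 6 features named by the rule lost their call without flowers 1 (adjusted p up to 0.412 for mtr-miR166a), as did all 4 families without flowers 1, flowers 2 or flower buds 2 (up to 0.271 for miR166).

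Roots were last compared with shoots. miR394 was at 165 ± 82.4 CPM in roots and 1461 ± 364 CPM in shoots (SD, n = 3 each; log2 fold change -3.13 ± 0.53, adjusted p = 3.95e-05), and miR319, miR167 and miR164 were also lower in roots (-2.19 ± 0.40, -2.08 ± 0.36 and -1.63 ± 0.32). miR172 was higher in roots, at 8715 ± 493 CPM against 2387 ± 449 CPM (1.87 ± 0.41), and miR156 lower (-1.16 ± 0.39). miR4415 was listed at 0 in shoots and was at least 26.1-fold higher in roots, and miR397 was also listed at 0 in shoots. miR5559 was listed at 0 in roots and was at 174 ± 76.2 CPM in shoots, and miR5368 fell by 4.03 on the log2 scale.

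In this comparison 3 of 5 auxin families fell (miR164, miR167 and miR393), and of the developmental list miR171 rose and miR164, miR319 and miR394 fell. Of copper families miR397 rose and miR398 fell (-1.89 ± 0.61). miR399 rose (2.45 ± 1.04), but 0 phosphate and sulfate families passed adjusted over the list alone. miR482 fell (-1.45 ± 0.38), as did the legume families miR4414 and miR5232, and neither small RNA machinery family passed. The other counts adjusted over the list alone did not differ. There were 59 features higher and 63 lower, with 41 and 83 under DESeq2's size factors, 76 and 52 under library size, and 42 and 76 under the authors' factors. Without shoots 2, 79 were called. Calls of miR171 and miR399 were lost with DESeq2's and the authors' factors and those of miR156, miR398 and miR482 with library size. Single libraries also ended the calls of miR398 (roots 1 or roots 3, adjusted p up to 0.0977), miR482 (roots 3 or shoots 2, up to 0.0828), miR156 (10 libraries, up to 0.0989), miR393 (6 libraries, up to 0.118) and miR399 (7 libraries, up to 0.163).

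By the tau index 51 of 323 features were concentrated in 1 tissue (tau of 0.85 or more, median 0.472). Roots held 44 of these, 39 of them without a family, young pods 3, stem 2, and flowers and flower buds 1 each. Shoots and mature leaves held 0. The filter works on CPM, so fewer reads are needed to pass it in a shallow library. Root libraries had 72853 to 150453 reads against 997119 in flowers 2, but mature leaves 3 was shallow too, at 74113. How far depth and the filter shape this split by tissue was not tested. The count depended on the features and the scale: 13 with exact features only, 28 with thinned libraries, 107 with linear CPM, 167 with the stricter filter and 962 with no filter. Without flowers 1 there were 90 and without flowers 2 there were 96.

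Mature miRNAs of 20 nt took 16.4% ± 2.41 of miRNA reads in stem (SD, n = 3), where the 20 nt miR319 member gma-miR319f_1ss17TC stood at 159302 CPM, against 2.79% ± 1.38 in young pods (n = 3) and 4.60% ± 0.616 in roots (n = 3; permutation p = 1e-05, the smallest these resamples give; adjusted p = 4e-05 by permutation). The 21 nt class held 70.2% to 82.2% of reads as tissue means. The 21, 22 and 24 nt shares did not pass (permutation tests, adjusted p = 0.0778, 0.114 and 0.0838). This turned with single libraries: the 21 nt share passed without roots 2, young pods 2 or flower buds 1 (0.0227, 0.0178 and 0.0399) and the 24 nt share without roots 2 or shoots 1 (0.0416 and 0.0345). The 21 nt share also passed with every entry as its own feature (0.0327), and the 21 and 22 nt shares without the most abundant family (0.0238 and 0.0345). None of the 12 listed animal miRNA families stood in the table. The reference set behind the names is not given in the sources used here, so this absence cannot tell whether RNA of another organism was present.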

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

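The tests with the authors' factors, summed entries, collapsed identical profiles, exact features and thinned libraries were chosen after the data were seen. Of 439 alternative values 383 lay within 1.5 times the reported count and 56 beyond, and the cause of those was not tested. Unfiltered data gave 327 calls for roots, 96 for flowers, 115 for young pods and 17 for flowers against flower buds, and 962 features by tau, with 1464 features tested. The stricter filter gave 107 for young pods, 159 for flower buds, 18 for flowers against flower buds and 167 by tau. With exact features only there were 94 calls for roots, 77 for roots against shoots, 18 for flowers against flower buds and 13 by tau, among 199 features tested. DESeq2 called 31 features in flowers, and every entry as its own feature gave 83. Flowers against flower buds was the least stable, with 9 calls reported, 14 with DESeq2's size factors, 19 with library size, 18 with the authors' factors, 27 with DESeq2, 24 with every entry, 14 with only both tissues fitted, 16 with entries summed and 22 with thinned libraries. By tau, linear CPM gave 107 features and thinned libraries 28. For the length shares, 2 lengths passed with every entry (20 and 21 nt) and 3 without the most abundant family (20, 21 and 22 nt). Leaving out each library in turn gave ranges of 222 to 254 calls over all tissues, 127 to 192 for roots, 25 to 49 for shoots, 76 to 103 for mature leaves, 68 to 111 for stem, 30 to 81 for flowers, 51 to 83 for young pods, 60 to 95 for flower buds, 90 to 107 for reproductive against vegetative tissues, 0 to 22 for flowers against flower buds (0 without flowers 1 or flower buds 3), 79 to 135 for roots against shoots, 35 to 96 by tau, 182 to 217 for the families and 1 to 3 lengths (3 without roots 2). The median log2 fold change of all features moved with the scaling, from -0.08 in roots to -0.75 with DESeq2's size factors, 0.55 with library size and -0.93 with the authors' factors, and from -0.41 to -0.85 with library size in mature leaves. Whether the replicate numbers pair the libraries stays open. Deviations of same-numbered libraries correlated at -0.27 to 0.28 over 57 pairs (mean 0.020, against -0.010 for pairs of other numbers). Of 20 libraries 11 correlated best with their own number, a count not set against the share that chance gives. The replicate block gave 231 calls over all tissues, 158 for roots, 43 for shoots, 92 for mature leaves, 101 for stem, 40 for flowers, 63 for young pods, 76 for flower buds, 96 for reproductive against vegetative tissues, 15 for flowers against flower buds, 111 for roots against shoots and 188 for the families. The tau index comes from no test and the length shares from a permutation test, and no block was fitted to either. Alternatives planned for tables with normalized values only did not apply. Depth limits rare miRNAs most in mature leaves 3, where a level under 61.0 CPM cannot be told from 0.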

Other observations

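The tests of the root-only features, of mature leaves 1, of other splits for flowers and for reproductive tissues, and of reads shared among precursors were chosen only after the results were seen. miR391 was at 756 ± 288 CPM in mature leaves (SD, n = 3), 623 ± 92.1 CPM in flower buds, 614 ± 8.03 CPM (n = 2) in flowers and 573 ± 463 CPM in young pods (308 CPM without young pods 1), at 11.2 ± 19.4 CPM in shoots and at 0 in roots. miR2119 was at 1471 ± 1537 CPM in mature leaves (584 CPM without mature leaves 1), 1452 ± 1492 CPM in young pods (669 CPM without young pods 2), 7.85 ± 13.6 CPM in shoots and 0 in roots. In shoots both were above 0 in shoots 3 alone. miR5368 was at 37786 ± 8842 CPM in mature leaves and 28743 ± 3176 CPM in shoots but 1757 ± 882 CPM in roots. Its tested features ran from 18 to 24 nt, and whether they are miRNAs or fragments of another RNA was not tested. As a family miR390, which starts the production of trans-acting siRNAs from TAS transcripts, passed in none of the 10 comparisons, with tissue means from 23698 ± 1104 CPM in mature leaves to 51633 ± 14172 CPM in young pods. Its member mtr-MIR390-p5 was called higher in young pods, at 92.4 CPM, a call lost without young pods 1 (44.5 CPM). ath-miR390a-5p differed over all tissues (edgeR quasi-likelihood F-test, adjusted p = 0.0105). The family miR1511, described mainly in legumes, also passed in none of the 10 comparisons.

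The balance between the 5′ and 3′ arms of the same listed precursor differed between tissues. Of 14 precursors with both arms above 0 in every library, 9 passed (limma F-test on log2 of the 5′ over the 3′ reads). The log2 ratio of mtr-miR166e-5p over mtr-miR166a went from -4.17 in flower buds to -7.47 in mature leaves (adjusted p = 0.00106). The smallest adjusted p, 1.17e-06, was that of aly-miR166g-5p_2ss5TC11TC over ath-miR166a-3p_L+1R-1, a precursor with an arm sequence on more than 1 line of the table. The lower limit of the table is argued against by the 6 of 9 precursors with at least 20 reads on both arms in every library that passed. Of 8 with unshared arms 5 passed, which argues against sharing of reads among the listed entries as the whole cause. Unshared means a sequence on a single line, whole values in every library and the values of no other entry. Reads of the same sequence from loci that are not listed could not be checked, since no genome was used. The 9 that passed exceeded the 3 that the highest of the other 99 assignments of libraries to tissues gave (1 of 100 as large). A hypothesis that arm choice or arm stability may depend on the tissue stays open, as do reads from unlisted loci and ligation bias, which were not tested.

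Among features without a family, 21 were seen in all 3 root libraries and in no other library, and held a mean of 2.26% of root reads. Depth argues the other way, since root libraries had 0.273 times the mean total of the others. Root-specific lentil miRNAs made from the listed precursors do not account for them as a set, since 4.76% lay exactly in their precursor. A candidate explanation, which stays open, is RNA of another organism living in or on roots. Of the 21, 95.2% did not lie exactly in the listed precursor, against 47.9% of the 94 other tested features without a family (Fisher's exact test, two-sided p = 4.43e-05). All 21 were also 18 to 20 nt long, against 40.4% of the 94. Features of the same length were not compared, so the test cannot tell origin from length and gives no support to this explanation. Breakdown products of longer root RNAs might look alike and were not tested apart from this.

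Of the 10 most abundant families 8 were higher in mature leaves 1 than in the mean of the other leaf libraries, with a median log2 ratio of 0.97. With library size alone the median was -0.0949, but these families held 84.7%, 78.2% and 77.8% of the reads of the leaf libraries, which holds their median near 0 under that scaling. Levels in this library and its composition factor therefore cannot be told apart. The library also had a lower share of reads in 18 and 19 nt features, 0.968% against 5.09% and 5.13%, and miR8175, with an 18 nt main member, had a log2 ratio of -2.14. With the factors taken from features of 20 nt or more the median was 0.611, between the bounds set for and against short fragments as the cause, which stays open. No biological explanation was tested, since the labels give no difference between these libraries.

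Assignments of the 20 libraries to the tissues at random, 100 with the real one, were used to ask whether chance could give as many calls. In each of 8 cases 1 of 100, the real one, was as large, so random assignment of single libraries seldom gave as many calls. The shuffles split up the libraries of a tissue, which may share a pool. Chance differences between pools are therefore not excluded. The real count and the highest other were 240 and 4 over all tissues, 168 and 54 for roots, 46 and 39 for shoots, 100 and 44 for mature leaves, 98 and 58 for stem, 67 and 57 for young pods, 77 and 52 for flower buds, and 198 and 31 for the families. For reproductive against vegetative tissues, whole tissues were split 3 against 4. Only 1 of 35 splits, the real one, was as large, but splits that mix the groups gave up to 86 calls against the real 105. For flowers, with 2 libraries, 3 of 100 were as large, a share under 0.05. The highest other count was 76 against the real 49, so chance is less likely but not excluded. For roots against shoots the 10 splits of 6 libraries are too few for a share under 0.05: the real split gave 122 calls, the highest other 0, and 1 of 10 was as large. The 10 splits of the flower and flower bud libraries are likewise too few: the real split gave 9 calls, the highest other 5, and 1 of 10 was as large.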
